A study of Zea mays with 2 samples.

How the data were processed

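Chromatin immunoprecipitation with sequencing (ChIP-seq) was applied to wild-type maize endosperm, the storage tissue of the kernel, at 15 days after pollination. The samples were 1 library made with an antibody against Opaque2 (O2), raised by the submitters in rabbits, and 1 control library made with non-specific rabbit IgG. Per the labels' protocols, both libraries came from sonicated nuclei, were amplified for 15 PCR cycles and were size-selected at about 500 bp including adapters. With 1 library per antibody no value here has a replicate error, and no test compares libraries.

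The submitters' processing notes name Bowtie2 without a version, and MACS2 in versions 2.0.10 and 2.1.0, with no statement of which version made which list. The assembly, the treatment of reads that map to several places, the treatment of duplicates and the threshold are not given in the sources used here. The authors deposited 2 peak lists of the same pair of libraries, one marked release 15 (the earlier list) and one marked release 26 (the later list). Names of peaks in the earlier list contain the word "uniq" and those in the later list do not. Coordinates are printed as each list gives them, counted from 1, and were never converted between lists.

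Per the file headers, each peak has a start, an end, a summit, a pileup (the signal of overlapping fragments at the summit), a fold enrichment over the peak caller's background, and p and q values. The deposited -log10 p and -log10 q values are the peak caller's, and they measure counting error in these 2 libraries only. In the later list the headers of both columns had been overwritten by a spreadsheet error. They were identified from their order and because the second of them equals the score in the deposited summit list. The deposited fold enrichment is the ratio (pileup + 1) / (background + 1) at the summit, so it is lower than pileup divided by background. Peak scores were used to describe, rank and filter peaks within a list.

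The 2 deposited summit lists are filed under the IgG sample. Each was compared with the peak list of the same release by name, chromosome, position within 1 bp and score. All 1686 summits of the earlier and all 2567 of the later release were those of the O2 peaks, at exactly the same position, so no list of IgG peaks was analysed here.

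The background behind each fold was recovered as (pileup + 1) / fold - 1. The Poisson p recomputed from this background differed from the deposited one by at most 0.00015 on the -log10 scale in the earlier list and 0.000129 in the later list, leaving out 1 peak of the earlier list whose p was too small to recompute. The backgrounds fell on the steps that the caller's windows allow. Of the later list, 1000 backgrounds (39.0%) were whole multiples of 0.979, taken as 1 IgG fragment at the summit, within 0.005 of a fragment. A further 736 (28.7%) were whole multiples for a 1 kb window, 642 for a 10 kb window (within 0.02 of a step), and 189 (7.36%) lay at the list's lowest value of 1.35, leaving none unexplained. In the earlier list the step was 0.995, the lowest value was 0.961, and the numbers were 658, 513, 442 and 73. Whether the control was scaled to the O2 library is not given in the sources used here, so these steps were not turned into a ratio of depths. Total read depth is unknown. This recovery of the background was added after the data had been seen. Intervals below cover counting error only, since PCR copies are not independent molecules.

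Peaks were counted per chromosome, and their density was taken over the span from the first to the last summit, because no genome of either release was used here. Before the data were examined a test was planned only over assembled chromosome lengths, with counts alone if these were lacking, so the test over the span was an addition made after the data had been seen. Exact Poisson 95% intervals were given for densities. Departure from an even spread was tested by placing the peaks 100000 times at random in proportion to span (two-sided, Benjamini-Hochberg over 10 chromosomes). Clustering was the share of peaks whose next summit lay within 10 kb, against 1000 random placements within each chromosome's span (two-sided). Correlations of fold with peak length and with pileup were computed across peaks, which are not independent replicates, with 100000 permutations.

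Gene features, O2 motifs and the planned gene lists were not examined, since the annotation at hand belongs to another assembly (Zm-B73-REFERENCE-NAM-5.0). By the rule set before the data were examined, the named peaks were therefore the 10 highest by fold and the 10 highest by -log10 q in the later list, and the 5 highest by fold in the earlier list. Stricter q and fold minimums, other distances, placement within 5 Mb of each peak and other ways to count peaks were also tried.

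A planned comparison of both lists matched peaks of identical chromosome, length, summit offset and pileup. A second one was added after the data had been seen: a peak of one list was paired with a peak of the other on the same chromosome if at least 5 neighbouring summits within 10 Mb lay at the same spacing, within 5 kb and in either direction, and each was the other's best partner. These values were not fixed in advance. Of 10 combinations of tolerance, neighbours and window tried on these lists, which linked 819 to 1444 peaks, the one that linked the most was used. When different chromosomes were paired, the 10 combinations linked 0 to 104 peaks. On simulated data (the later list of 2555 chromosomal peaks against a thinned copy with drifting positions) it found 96.9% of 1513 shared peaks, and 1.21% of its matches were wrong. The simulated copy held no reversed or moved stretches, so these rates may not hold for the deposited lists. The placement test called 1 of 50 simulated even lists and 20 of 20 lists with added close pairs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.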

Results

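Opaque2 is a basic leucine zipper transcription factor of the maize endosperm, known for activating zein storage protein genes. Its binding to chromatin in wild-type endosperm at 15 days after pollination was profiled in 1 anti-O2 library, with 1 IgG library as the control. The question was where in the genome O2 binds. The reads of this pair of libraries were called as O2 peaks on 2 genome releases, giving an earlier list (release 15) of 1686 peaks and a later list (release 26) of 2567 peaks. Peak scores are the authors' values, and neither the peaks nor their scores have a replicate check. The total depth of the libraries is unknown, and the assembly behind each release is not given in the sources used here. Without a genome of these releases, peaks are named by position and not by gene.

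O2 pileup at the summits was far above the IgG-based background at most sites. In the later list the median summit carried a pileup of 29 fragments (quartiles 20 and 53) over a background of 2.94 in units of pileup (quartiles 2.07 and 3.91). The median fold enrichment was 7.62 (quartiles 5.48 and 13.1) and the highest was 63.2. The earlier list had a median pileup of 28 over a background of 2.50, with a median fold of 8.03 and a highest fold of 85.9. Enrichment of at least 20-fold was listed for 318 later and 199 earlier peaks. Every peak passed the peak caller's test, with a largest q of 0.0444 in the later and 0.0468 in the earlier list. Peaks were listed because pileup exceeded this background, so the excess itself is built in and only its size is described.

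Binding signal was spread unevenly over the sites. The 10% of later peaks with the most signal (257 peaks) held 30.6% of all pileup above background, and the corresponding 169 earlier peaks held 29.1%. Peaks were narrow, with a median length of 375 bp in the later list and 412 bp in the earlier one. The shortest were 265 and 296 bp. Across peaks of the later list, fold correlated with length (Spearman rho = 0.782, Pearson r = 0.721) and with pileup (rho = 0.807, r = 0.779). For earlier peaks the values were rho = 0.761 and r = 0.674 for length and rho = 0.783 and r = 0.741 for pileup. Each of the 4 relations had a permutation p of 1e-05 by both measures, the smallest that 100000 permutations can give, which Benjamini-Hochberg adjustment over the 4 relations leaves at 1e-05. Both kinds of relation are partly built in by the peak calling, since fold is computed from pileup and a called interval reaches further where the summit is higher, so they describe the scores and not the binding.

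**Figure D1:**
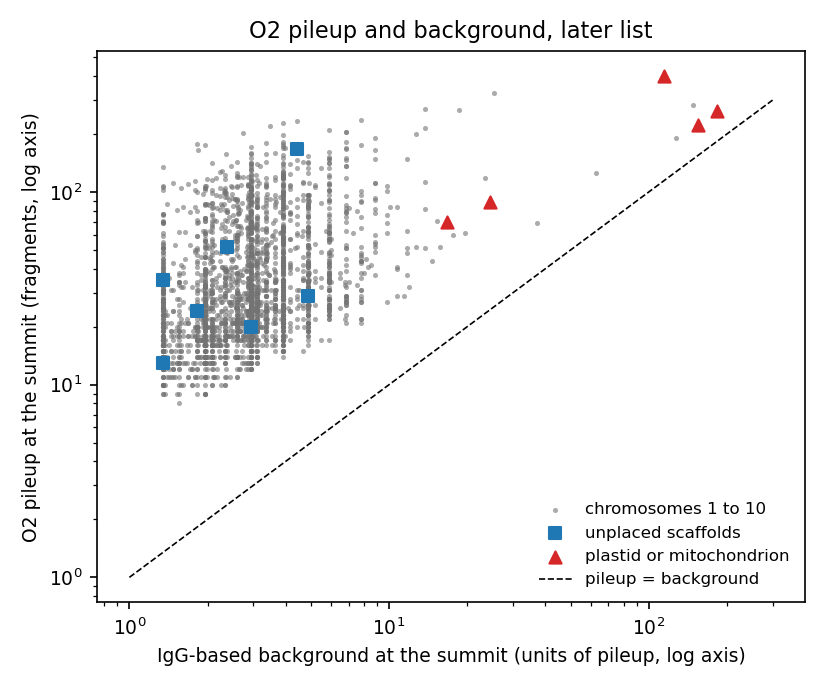
O2 pileup at each summit of the later list (vertical, fragments) against the recovered IgG-based background (horizontal, in units of pileup), both on log axes, with 1 point per peak. Of the 2567 peaks, 90.2% lie at a background under 5, while 10 lie at 20 or more, 6 of them on chromosomes and the others on plastid or mitochondrial sequence (red triangles; blue squares are unplaced scaffolds and the dashed line marks equal values).

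The highest fold in the later list, 63.2, was at 132241462 to 132242092 of chromosome 4, where a pileup of 177 stood over a background of 1.82 (-log10 q = 272.7; 1 is added to both before fold is taken). The next was a peak on chromosome 5 at 170565902 to 170566501, with a fold of 59.9 and a pileup of 176 over 1.96. A peak on chromosome 8 at 158791325 to 158791957 had a fold of 58.4 with a pileup of 165 over 1.84. The next 2 lay on chromosome 2. One, at 45002575 to 45003100, had a fold of 57.9 and a pileup of 135 over the list's lowest background of 1.35, and the other, at 237488571 to 237489229, had a fold of 54.4 and a pileup of 203 over 2.75. Chromosome 3 held a peak at 118016974 to 118017564 (fold 49.4, pileup 220) and one at 203271152 to 203272089 (fold 46.8, pileup 229). The latter was the longest peak of the list, at 938 bp, and had its highest -log10 q, 302.4. The other peaks among the top 10 by fold were on chromosome 4 at 239739711 to 239740264 (fold 47.0, pileup 157), on chromosome 6 at 153979262 to 153979828 (fold 46.4, pileup 108) and on chromosome 1 at 232655189 to 232655711 (fold 46.2, pileup 141).

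Ranking by -log10 q gave 6 of the same peaks and 4 others. Chromosome 4 contributed a peak at 36375025 to 36375632, with a pileup of 234 and a -log10 q of 299.6, and a peak at 50597031 to 50597678, with a pileup of 197 and a -log10 q of 248.2. Both had folds above 40, at 43.4 and 40.3. A peak on chromosome 7 at 61550786 to 61551339 had a pileup of 236 and a fold of only 26.8, over a background of 7.83, which is 8 steps of 1 IgG fragment. A peak on chromosome 1 at 118001049 to 118001706 had the highest pileup of the named peaks, 270, over a background of 13.7, which is 14 such steps, and a fold of 18.4.

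In the earlier list the highest fold, 85.9, was on chromosome 8 at 159248417 to 159249032, where a pileup of 176 stood over a background of 1.06. Its -log10 q of 310.2 was also the highest of that list. It was followed by a peak on chromosome 4 at 36341932 to 36342491 with a fold of 73.9 and a peak on chromosome 1 at 232593221 to 232593779 with a fold of 57.5. The next 2 were both on chromosome 2, at 236663811 to 236664461 (fold 54.2) and at 1463047 to 1463574 (fold 52.0). The positions of the 2 lists are not on the same scale: only 32 of 1681 earlier chromosomal peaks overlapped a later peak at the printed coordinates.

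O2 peaks were found on all 10 chromosomes at similar density. In the later list, 2555 peaks lay on chromosomes 1 to 10, at 1.25 per Mb of span. The density ran from 1.08 per Mb on chromosome 6 (181 peaks, 95% interval 0.929 to 1.25) to 1.37 on chromosome 2 (324 peaks, 1.22 to 1.52), and chromosome 1 had the most peaks, 382. Among earlier peaks it ran from 0.680 on chromosome 10 (101 peaks, 0.554 to 0.827) to 0.911 on chromosome 3 (211 peaks, 0.792 to 1.04). An even spread by span was not rejected in either list (permutation p = 0.235 for the later and 0.274 for the earlier list). No chromosome departed from it after adjustment in this permutation test, and 1 chromosome per list did at an unadjusted p under 0.05, namely chromosome 6 in the later list (p = 0.0447, adjusted p = 0.364) and chromosome 10 in the earlier one (p = 0.0458, adjusted p = 0.458). This test over the span was chosen after the data had been seen.

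**Figure D2:**
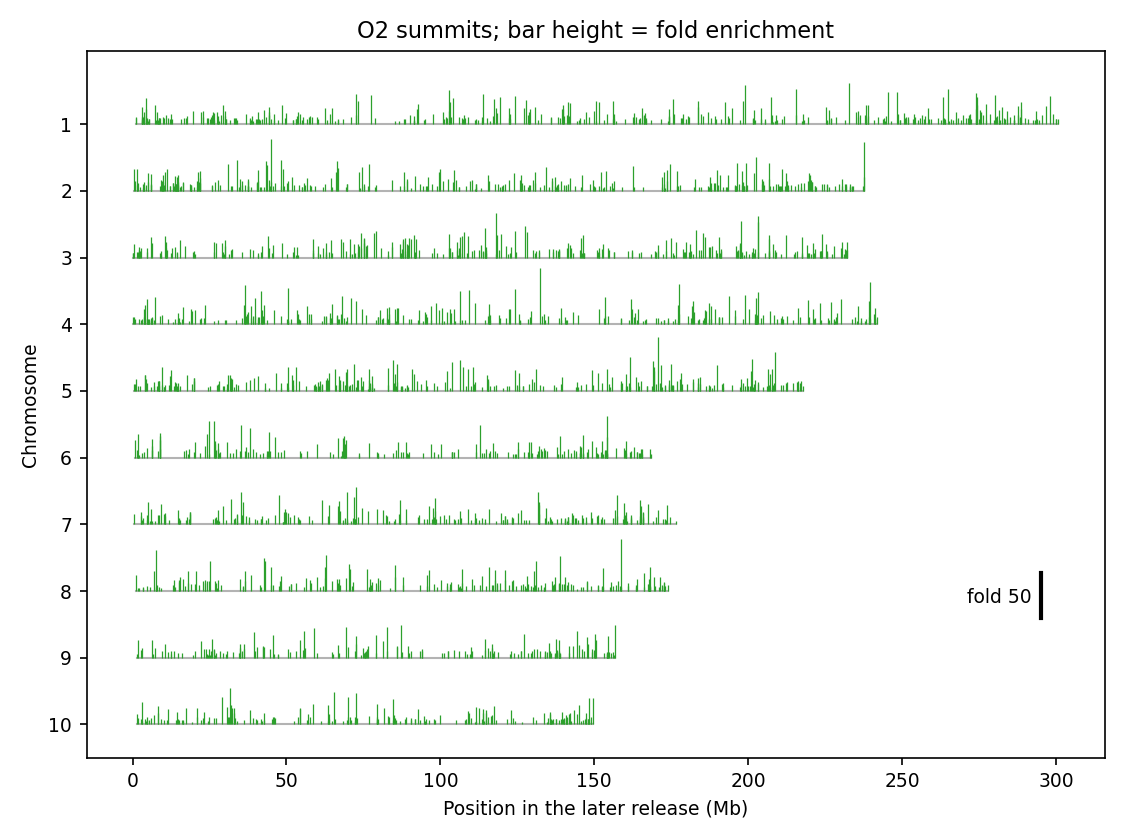
Map of the O2 summits of the later list along chromosomes 1 to 10 (horizontal, position in Mb as listed), with each bar's height proportional to the fold enrichment a scale bar of fold 50, and grey lines from the first to the last summit. Peaks cover every chromosome, and the highest bar stands on chromosome 4 at fold 63.2.

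Neighbouring peaks lay close together more often than random placement gave. In the later list, 60 of 2555 peaks (2.35%) had the next summit within 10 kb, against a mean of 31.7 in random placements and at most 51 in any of 1000. The number in the earlier list was 29 of 1681 (1.73%), against a mean of 13.9 and at most 26. Both had a two-sided permutation p of 0.002, the smallest that 1000 placements can give. Close neighbours were nearly always pairs. Only 3 groups of 3 peaks were found in the later list and none in the earlier. They ran from 62962285 to 62973979 on chromosome 3, with folds of 15.7, 4.50 and 5.94, from 140459181 to 140466813 on chromosome 7, with folds of 6.88, 5.91 and 4.07, and from 172582869 to 172595440 on chromosome 8, with folds of 9.47, 5.61 and 9.90. These groups were chosen after their values had been seen, and the number of such groups was not compared with random placement.

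A few listed peaks stood on a high background, and most of these, on organelle sequence and on chromosomes, were weakly enriched. They were chosen after their values had been seen. The later list had 5 peaks on plastid and mitochondrial sequence. Their folds were 3.55, 1.45 and 1.43 on the plastid and 4.02 and 3.48 on the mitochondrion. The strongest pileup of either list, 429, was on the mitochondrion at 252000 to 252510 of the earlier list, over a background of 127.8 (fold 3.34). On the chromosomes, 6 later peaks had a background of at least 20, and 4 of them had a fold under 3. These were on chromosome 1 at 8186170 to 8186532 (fold 1.98), on chromosome 2 at 172725549 to 172725834 (fold 1.49), on chromosome 6 at 67873245 to 67873550 (fold 1.91, with a pileup of 283 over 147.8) and on chromosome 8 at 167900799 to 167901094 (fold 1.83). The other 2, both on chromosome 8, were at 60901561 to 60902026 (fold 4.86) and at 100135827 to 100136412, where a pileup of 327 over 25.4 gave a fold of 12.4. Among earlier chromosomal peaks, 2 had a background of at least 20, one on chromosome 6 at 67712769 to 67713064 (fold 1.96) and one on chromosome 7 at 49140277 to 49140899 (fold 12.2). Of all 21 later peaks under fold 3, 15 had a background under 20.

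The later list held 1.52 times as many peaks as the earlier one. The lists also differed in their shortest peaks and in their lowest backgrounds (0.961 and 1.35), and whether they shared a read filter or a caller version is not given in the sources used here. The ratio was 1.53 among peaks with a -log10 q of at least 5 and 1.54 among those with at least 10. No peak had the same chromosome, length, summit offset and pileup in both lists, against a mean of 0.219 when chromosome names were permuted (one-sided permutation p = 1), so this comparison could not link the lists. The spacing to neighbouring summits, a comparison added after the data had been seen, linked 1444 peaks, which is 85.9% of the earlier and 56.5% of the later chromosomal peaks. This was the highest number among 10 combinations of settings tried, and the lowest was 819. Pairing different chromosomes in the same way linked at most 18. Across linked peaks, fold in one list followed fold in the other (Spearman rho = 0.860, Pearson r = 0.867 on the log2 scale, each with permutation p = 0.001, the smallest that 1000 permutations can give). Both lists come from the same libraries, so this relation is partly built in and is no replicate check of the binding. Of the 14 distinct named later peaks, 11 had a partner.

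The peak with the highest fold in the later list, on chromosome 4, had a pileup of 177 there and 144 in the earlier list. The highest of the earlier list, on chromosome 8, had 176 there and 165 in the later. The chromosome 2 peak at 45002575 to 45003100 had a pileup of 135 in the later list and only 34 in the earlier, with folds of 57.9 and 17.8. The chromosome 3 peak at 118016974 to 118017564 had 220 and 123. The 1111 later chromosomal peaks without a partner were weaker, with a median -log10 q of 10.3 against 23.8 for linked peaks, and the 237 earlier ones without a partner had a median of 5.63 against 17.7. These earlier values depended on the setting: 585 peaks with a median of 10.7 were left without a partner with 3 neighbours within 500 bp, and 862 with a median of 12.6 with 2 neighbours within 50 bp (medians of linked peaks 18.5 and 18.6).

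**Figure D3:**
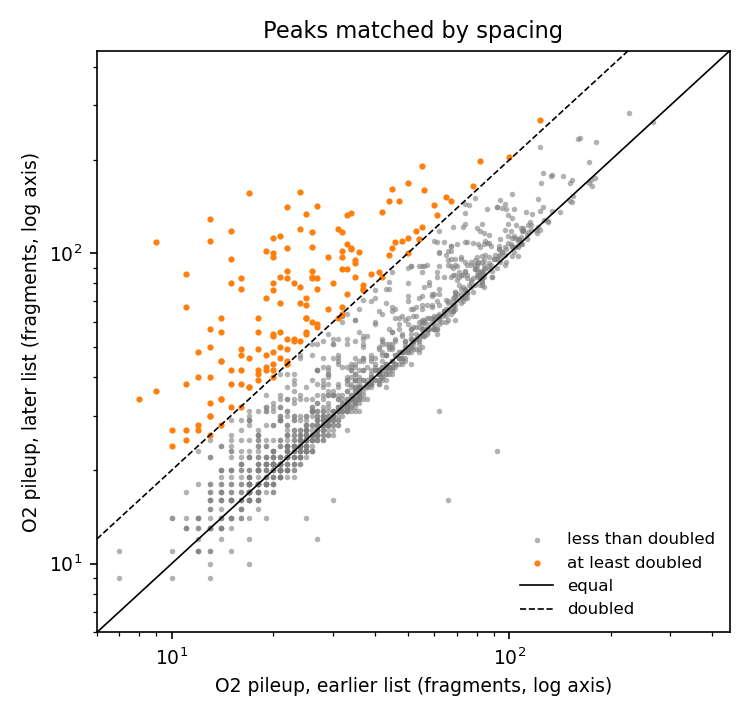
O2 pileup of the 1444 linked peaks in the earlier (horizontal) and later list (vertical), in fragments on log axes, with 1 point per peak and lines for equal and doubled values. Most points lie near the line of equal values, and 162 (orange) lie at or above the doubling line.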

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

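The settings of the spacing comparison, the count without high-background peaks, the test over chromosome span and the shares of the outer span were chosen after the data had been seen. Of 63 alternative values, 58 kept the direction and the side of the threshold or, for counts, stayed within 1.5 times of the reported number. The exceptions were as follows. The number of earlier peaks was 1113 at a -log10 q of at least 10, because fewer peaks pass that minimum. The later list fell in much the same way, from 2567 to 1714, but stayed narrowly within 1.5 times. Peaks of the same chromosome, length and summit offset in both lists numbered 3 when pileup could differ by 10% (permutation p = 0.48), and 1444 peaks were linked when neighbour spacing was used in its place. Of the 10 spacing settings, the one used linked the most, and 2 others linked over 1.5 times fewer: 819 with 2 neighbours within 50 bp and 961 with 3 neighbours within 1000 bp over 3 Mb. Across the 10, the median log2 pileup ratio of linked peaks ran from 0.08 to 0.11 and the share with doubled pileup from 9.52 to 11.6%. Clustering kept its direction, with p from 0.002 to 0.018, at 1 kb, at 100 kb, at a -log10 q of at least 5 and with placement within 5 Mb. The 11 planned settings on gene features and motifs were not run, because no genome or annotation of either release was used here. Depth is unknown, and 1 library per antibody allows no leave-one-out check.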

Other observations

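The tests on chromosome ends and on the larger number of later peaks were chosen after their results had been seen in whole or in part, and those on neighbouring peaks before, except for the pileup similarity of earlier neighbours. O2 peaks were denser toward the ends of the chromosomes. Leaving out the first and last peak of each, the outer 25% of the span on each side held 56.9% ± 3.75 (SD, n = 10 chromosomes) of later peaks and 56.9% ± 3.78 of earlier peaks, where an even spread gives 50%. The share was above 50% on 9 of 10 chromosomes in both lists (exact two-sided sign-flip permutation test over chromosomes, p = 0.00391 in each). Chromosome 3 was the exception, at 49.7% and 48.8%, and chromosome 6 had the highest later share, 62.6%. The outer 10% on each side held 25.8% of later and 25.1% of earlier peaks, against 20% for an even spread (exact permutation p = 0.00195 and 0.00391). Peaks in the outer 25% were not shown to differ in strength: the median fold per chromosome averaged 7.57 ± 0.334 (SD, n = 10) there and 7.83 ± 0.710 in the inner part of the later list (exact permutation p = 0.359). How genes or mappable sequence are distributed in these releases was not examined.

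Unplaced sequence also carried O2 peaks. One unplaced scaffold of the later list held 5 peaks, with folds of 15.3, 5.09, 31.2, 5.34 and 15.7. The first 3 were 19531 and 85214 bp apart. The 3 peaks on unassigned sequence in the earlier list were 19595 and 85166 bp apart, with folds of 13.3, 5.02 and 14.5. The pileup at the third was 71 in the earlier and 168 in the later list. These peaks were chosen after their values had been seen.

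The later list held 2567 peaks against 1686 from the same libraries, and neither a biological explanation nor a changed read filter, caller version or caller setting was tested for this. How far weak sites near the calling threshold account for the added peaks could not be settled. Of the 1111 later peaks without a partner, 568 had a -log10 q of at least 10, against 237 earlier peaks left without one. The outcome of this comparison was fixed for any linking of peaks in pairs. The later list had 1706 chromosomal peaks at that level, more than the 1681 chromosomal peaks of the whole earlier list. Under any such linking some later peaks at that level lack a partner. By that narrow margin the counts argue against weak sites as the whole cause, but they do not give the share of weak sites. Since the outcome was fixed, finding it in all 10 spacing settings adds nothing. That test replaced a first one, after its outcome had been seen, which asked whether the median -log10 q of later peaks without a partner (10.3) lay below the lower quartile of linked ones (11): it did, in favour of weak sites, in the setting used and in 4 of the 10 settings in all. More reads at every site cannot be settled. The median log2 pileup ratio of linked peaks was 0.107 (quartiles 0 and 0.446), between the bounds of 0.1 and 0.3 set for it. It was under 0.1 in 2 of the 10 settings. Pileup was higher in the later list at 932 of the 1444 linked peaks, lower at 341 and equal at 171. The shortest peaks were 296 bp in the earlier and 265 bp in the later list, so the caller's fragment length may differ. A shorter length would lower the pileup of the same reads, so it would not by itself give the higher values at those 932 peaks. It may account for some of the 341 lower ones. The median ratio still lay between its bounds, so these values do not decide the question. A candidate explanation is that reads were gained at a subset of sites, tested only at linked peaks and not at the 1111 later ones without a partner: pileup at least doubled at 11.2% of linked peaks (162, exact 95% interval 9.64 to 13.0%) and at least halved at 0.277%. A linked peak had to be called in both lists, so sites that lost pileup may be among the 237 earlier peaks without a partner. The low share of halved peaks may therefore come partly from the linking.

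At the 162 doubled peaks the median background was 1.77 in the earlier and 2.94 in the later list, against 2.87 and 2.96 at the other linked peaks, while the lowest background of all peaks was 0.961 and 1.35. The median log2 ratio of fold over all linked peaks was 0.02. The largest of these gains was on chromosome 7, where the summit at 126264040 had a pileup of 9 in the earlier list and its partner at 126298996 had 109 in the later list, with backgrounds of 0.995 and 5.87. The gains named here were picked for their size. On chromosome 4 the pileup was 13 at 238744348 and 129 at 239287929, and on chromosome 7 it was 17 at 131715858 and 157 at 131748611, where the fold was 9.18 and 36.1.

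Neighbouring peaks lay within 10 kb of each other more often than placed by chance, and no biological explanation was tested. One site split into neighbouring calls is argued against in the later list, where 51 spacings of 1 to 10 kb exceeded the highest of 1000 placements, 45, but stays open in the earlier list, where 23 lay within the placements' range of up to 26 (permutation p = 0.006). Uneven density over stretches much longer than 5 Mb is argued against for later peaks. Their share of 2.35% exceeded the highest, 2.04%, when they were placed within 5 Mb of their own position. The 29 earlier peaks equalled the highest placement (mean 15.1, permutation p = 0.004), which by the bound set beforehand leaves it open there. Unevenness over shorter stretches is removed by this placement, so it stays open in both lists. Reads shared between near-identical neighbouring copies are a candidate explanation: the median absolute log2 pileup ratio of the 51 neighbour pairs of the later list was 0.68, just under the 5% point of random pairs of the same chromosome, 0.70, with a random median of 0.94, and duplicated sites that are both bound could give the same similarity. The 23 earlier pairs, compared after the later ones had been seen, gave 0.67, between the 5% point of 0.61 and the random median of 0.91, which decides nothing there, and the lists were not tested against each other; earlier peaks clustered 2.09 times as often as placed, against 1.89 times for later peaks.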
